A study of Mus musculus with 9 samples.

How the data were processed

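RNA of RAW-Blue mouse macrophage cells was sequenced as paired 100-base reads after total RNA extraction, per the labels' protocols, with adapter and low-quality reads removed by SOAPnuke. The submitters' processing notes name STAR 2.7.10a, RSEM 1.3.1 and the genome build GRCm38. The deposited tables hold, per the file headers, expected counts and TPM for 50600 genes with Ensembl identifiers and symbols. The deposited expected counts are estimates that divide reads between genes that share sequence and need not be whole. The deposited TPM values are the authors' counts scaled for transcript length to a sum of 1000000 per library. Whether the library kit kept the strand or selected polyadenylated RNA is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart.

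The labels name 9 samples in 3 groups, None, LPS and LPS-PjELNs, with 3 replicates each. Each table has 6 library columns whose names matched the None and LPS labels. The other 12 library columns carry names that match no label and were not used in any step. No column could be given to the LPS-PjELNs samples, so the planned comparisons of LPS-PjELNs with LPS and with None, and the planned count of LPS-responsive genes that the vesicles move, were not made. The planned fit of all 9 libraries was therefore made on 6, and fitting only those 6 libraries, which had been listed as an alternative, gives the same fit.

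Expected counts were rounded to whole numbers. Libraries held 14650843 to 17665200 counts, of which 0.0231% to 0.0318% fell on 530 genes without a symbol, which were kept under their identifiers. Of all genes 31727 had 0 counts in the 6 libraries. Of the identifiers 50376 were found in the reference gene name table. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, with a count minimum of 10 and a total of at least 15, which left 11916. Libraries were scaled by TMM. A quasi-likelihood model with group as its single term was fitted (glmQLFit) and tested two-sided (glmQLFTest), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The biological coefficient of variation was 8.32%. CPM values use TMM-scaled library sizes, SDs are over 3 libraries, and folds are 2 to the power of the fitted log2 fold change. Where a group had 0 counts in every library, the fold was computed against a floor of 3 counts over the group and is a lower bound. Where it had 1 to 3 counts, the ratio of counts is given with an exact 95% interval. Intervals and floors cover counting error only, since reads are not independent molecules.

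In simulated counts for the LPS against None comparison, with real means and library sizes and 200 genes changed among 11818 tested, edgeR recovered 40% of genes changed by 0.5 on the log2 scale, 94% at 1, 98% at 2 and 100% at 4, with 4.05% of calls false. The simulation gave every gene the same preset dispersion, and far fewer genes changed in it than in the data. Its recovery and share of false calls are therefore a check of the steps and not an estimate for this comparison. Libraries of a group were compared before averaging, and each pair differed by more than sampling noise, with a chi-square per degree of freedom from 3.32 to 17.54. The main axis of variation between libraries held 90.9% of the variance and separated the groups, and the next held 3.23%, with LPS replicate 1 at 23 and the other LPS libraries at -7.5 and -16.

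Before the data were examined, 42 gene lists, the test designs, the alternatives and a rule for named genes were fixed. The lists cover inflammatory cytokines, chemokines, interferon-stimulated genes, NF-kappaB targets, Tlr4 signalling and its negative regulators, antimicrobial effectors, antigen presentation, macrophage states, osteoclast genes, stress responses, sterol and energy metabolism, cell cycle, ribosomes, small RNA machinery, nucleic acid sensors, cell death, immediate early genes, complement, adhesion, mitochondrially encoded genes, histones and markers of other cell types. All 978 entries were found in the files, 19 of them through a RefSeq synonym. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over 35 lists. The test fry of limma, planned beside camera, was run on the same lists with the same adjustment. The text names a fixed panel of 14 cytokine and effector genes, genes among the 10 largest increases and the 10 largest decreases with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups (predicted genes and pseudogenes left out), up to 4 members of each list with the largest changes, and Tlr4, Ly96 and Cd14. Other list members are named as examples chosen after their values were seen.

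The alternatives were RLE size factors in edgeR, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a replicate block, limma on TPM values, and leaving out each library in turn. Limma was run on log2(TPM + 1) with and without a filter on a mean TPM of 1, and on log2(TPM + 0.1) with that filter. Scaling by library totals alone, and a screen of all list members for calls that change when 1 library is left out, were chosen after seeing the data. Sequence shared between genes was measured as shared 31-mers of the GENCODE transcripts of GRCm38, neighbouring genes were compared with 10000 permutations of the labels over the gene order, and non-coding genes were compared with the 20 protein-coding genes nearest in expression, with 2000 bootstrap resamples, in Python 3.11.15. Those steps were tested on simulated data. Coordinates are those of the files on GRCm38, counted from 1.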

Results

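RNA was sequenced from RAW-Blue cells, a mouse macrophage line that carries a reporter for inflammatory signalling. The labels describe 9 samples in 3 groups of 3, namely cells with no treatment (None), cells given lipopolysaccharide (LPS) at 1 µg/ml for 24 hours, and cells given nanovesicles of the plant Peucedanum japonicum for 16 hours before the same LPS stimulus (LPS-PjELNs). LPS is a component of the outer membrane of Gram-negative bacteria and the ligand of the receptor Tlr4. The libraries analysed here were the 3 of the None group and the 3 of the LPS group, and the LPS-PjELNs group was not analysed here because no column name could be matched to its labels. The values were estimated counts per gene, and their totals ran from 14650843 in LPS replicate 2 to 17665200 in None replicate 3. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

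The comparison of LPS with None asked which genes respond to the stimulus against which the vesicle treatment was set. LPS-stimulated cells had far higher levels of transcripts for secreted inflammatory proteins, among them the granulocyte growth factor Csf3, the interleukins Il1a and Il1b, and the chemokine Ccl5. Enzymes that make nitric oxide (Nos2), prostaglandins (Ptgs2) and itaconate (Acod1) rose, as did most interferon-stimulated and NF-kappaB target genes. Nearly all genes of mitosis on the list fell, as did most genes of DNA replication and most genes encoded in the mitochondrial genome. Of 11916 genes tested, 8232 (69.1%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4052 higher and 4180 lower in LPS. At least 2-fold changes were found for 2734 genes, 1327 of them higher and 1407 lower. Increases of at least 10-fold were found for 268 genes and decreases of that size for 93. In 8774 genes (73.6%) the values of the 3 LPS libraries did not overlap those of the 3 None libraries, where chance gives 10%. The share of higher genes among those changed was 49.2%, and it was 30.6% when libraries were scaled by their totals alone and 35.5% on TPM values. Those scalings moved the log2 fold changes of single genes by a median of -0.26 and -0.20, so small changes are read relative to that shift.

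Every tested gene of the inflammatory panel was higher in LPS. The cytokine gene Tnf (chromosome 17, 35199381 to 35202007, GRCm38) rose 9.58-fold, from 74.1 ± 13.1 to 711 ± 56.9 CPM (SD, n = 3). Il1b (chromosome 2, 129364570 to 129371139) rose 5129-fold, from 0.333 ± 0.129 to 1745 ± 995 CPM. Its neighbour Il1a (chromosome 2, 129299610 to 129309972) went from 0.0345 ± 0.0298 to 565 ± 304 CPM, a ratio of counts of 16180 with a 95% counting interval from 4480 to 134000. Csf3 (chromosome 11, 98701263 to 98703629) had 0 counts in the None libraries and 933 ± 48.6 CPM in LPS, which was at least 17770-fold higher against a floor of 3 counts over the group. Il6 (chromosome 5, 30013114 to 30019975) stayed low, at 3.80 ± 1.76 CPM in LPS against 0.0172 ± 0.0298 CPM in None, with a ratio of counts of 217.7 and an interval from 38.5 to 8650. Its fitted log2 fold change was 7.25 and became 8.92 without None replicate 2, which held the single Il6 count of its group. Without that library Il6 had 0 counts in None, so the value of 8.92 depends on the prior count of the fit. The chemokine genes Ccl5, Ccl2 and Cxcl10 rose 582.5-fold, 241.0-fold and 52.7-fold, and Il1rn, which encodes the antagonist of the interleukin receptor, rose 31.8-fold. Nos2 rose 4306-fold to 485 ± 107 CPM, and the log2 fold change of Nos2 was 12.07, or 12.99 without None replicate 1. Ptgs2 rose 201.0-fold to 5812 ± 1830 CPM and Acod1 908-fold to 3518 ± 783 CPM. Adjusted p-values of the panel from edgeR's quasi-likelihood test lay between 4.05e-12 for Csf3 and Acod1 and 1.57e-06 for Il6. Il12b had 0 counts in None and 3 in LPS, Il10 had 3 and 4, and neither difference was detectable at this depth.

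**Figure D1:**
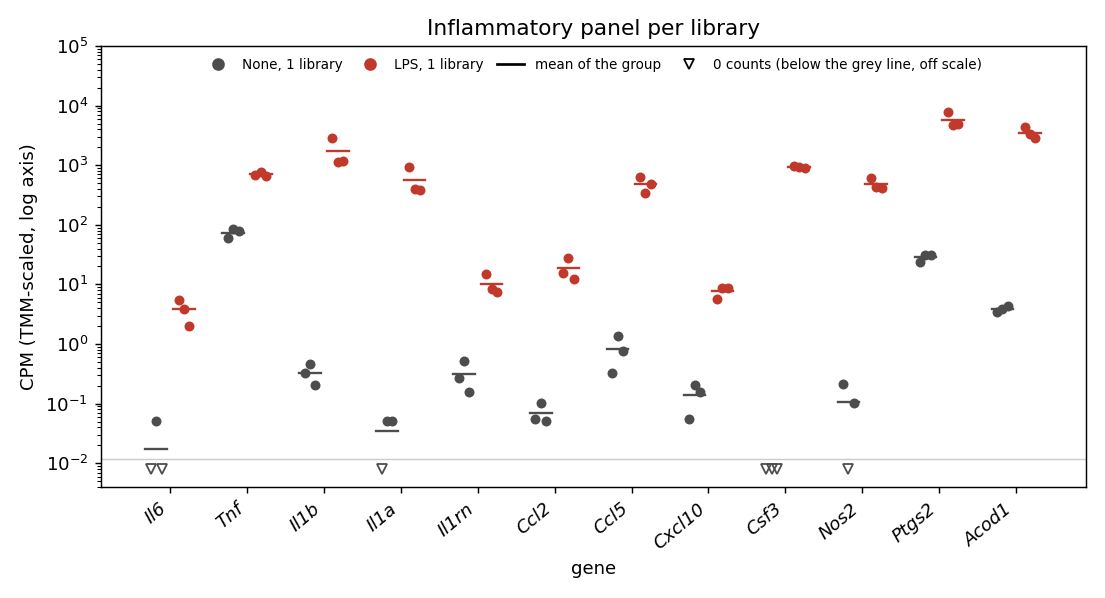
CPM of the 12 tested panel genes in each library on a log axis, with None in grey and LPS in red. Points are single libraries, horizontal bars are group means of 3 libraries, and open triangles below the grey line stand for 0 counts; the LPS points lie above the None points for every gene shown, with Tnf rising 9.58-fold and Csf3 at 0 counts in None.

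By fitted log2 fold change, the largest increases outside the panel were those of the alarmin Il33, the cystatin family gene Cstdc4, the iron-siderophore binding protein Lcn2, Urah, the membrane glycoprotein Pdpn and the collagen gene Col5a3. Where None had 0 counts, the fitted value depends on the prior count of the fit. The lower bounds given below do not secure the place of Lcn2, Urah and Col5a3 in this ranking. Il33 (chromosome 19, 29925114 to 29960718) went from 0 counts to 454 ± 300 CPM and was at least 8682-fold higher. LPS replicate 1 held 798 CPM of Il33 and the other LPS libraries 317 and 247, and the fitted log2 fold change of Il33 went from 15.87 to 15.22 without LPS replicate 1. Both fitted values rest on 0 counts in None and depend on the prior count of the fit. LPS replicate 1 also held 2893 CPM of Il1b against 1150 and 1192, and 915 CPM of Il1a against 402 and 377. Lcn2, Urah and Col5a3 also had 0 counts in None and were at least 917-fold, 691-fold and 399-fold higher. Cstdc4 reached 212 ± 24.1 CPM from a single count in None, with a ratio of 12110 and an interval from 2170 to 478000. Its fitted log2 fold change was 13.04. Without None replicate 2, which held that count, it was 14.72 and depends on the prior count of the fit. Cstdc4 belongs to a family of near-identical neighbours, so the division of its reads is uncertain. Pdpn rose 2886-fold to 275 ± 74.3 CPM.

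The largest decreases included Trf, which encodes the iron carrier transferrin, the transcriptional repressor gene Cbfa2t3, the lipid receptor genes S1pr1 and Lpar5, and Kmo, an enzyme of tryptophan breakdown. Trf (chromosome 9, 103204001 to 103230273) fell 44.6-fold, from 19.6 ± 0.21 to 0.431 ± 0.331 CPM, and the log2 fold change of Trf went from -5.48 to -6.24 without LPS replicate 3. Ranbp3l fell 44.2-fold, S1pr1 39.8-fold, Kmo 30.1-fold and Lpar5 19.1-fold, and Cbfa2t3 had a log2 fold change of -5.32. S1pr1 (chromosome 3, 115710433 to 115715072) went from 78.6 ± 15.1 to 1.97 ± 0.144 CPM, with an adjusted p of 9.59e-11 by edgeR's quasi-likelihood test. The leukocyte actin-binding protein gene Lsp1 fell 18.2-fold from 277 ± 15.3 CPM, and Rgs2, a regulator of G protein signalling, fell 17.2-fold from 143 ± 9.86 CPM.

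Secreted inflammatory mediators rose as groups. Of 17 inflammatory cytokine genes tested, 16 rose and none fell, including Lif (log2 fold change 10.35), Il27 (5.65) and Osm (3.54), while Tnfsf9 was not called at -0.13 but was called at -0.32 without LPS replicate 3. All 12 chemokine genes tested rose, among them Ccl4 at 7.02, Cxcl2 at 7.80 and Ccl5 at 9.19, while the call of Cxcl16 at 0.28 was lost without None replicate 2 (0.23), None replicate 3 (0.21) or LPS replicate 1 (0.22). Camera with Benjamini-Hochberg adjustment over the lists gave 1.73e-08 for the cytokines and 1.23e-06 for the chemokines. The first list had an adjusted p = 0.203 with an estimated correlation and the second an adjusted p = 0.166 with an estimated correlation. Interferon-stimulated genes rose in 36 of 39 tested, led by the ubiquitin-like modifier Isg15 (8.65), Rtp4 (8.39), the transcription factor Irf7 (7.73) and the nucleotide-binding protein gene Oasl1 (7.26). Ifit2 (-0.37), Slfn8 (-0.35) and Ifi47 (0.25) were not called over all genes tested, although Ifit2 (-0.90) and Slfn8 (-0.51) were called lower without LPS replicate 2. Camera's adjusted p was 1.62e-13 for this list, with an adjusted p = 0.254 with an estimated correlation. Effector genes of nitric oxide, prostaglandin and antimicrobial defence rose in 15 of 19, among them the prostaglandin synthase Ptges (5.95), the arginine-supplying enzyme Ass1 (4.40) and Slpi (5.94). The phagocyte oxidase subunits Ncf1 and Ncf4 lay at 0.13 and -0.01 and were not called. Camera gave an adjusted p of 4.38e-07 for the effectors, and the adjusted p = 0.166 with an estimated correlation.

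NF-kappaB target and feedback genes rose in 27 of 29 tested, with the inhibitors Nfkbia (3.50) and Nfkbiz (3.68), the adaptor Traf1 (4.02) and the membrane remodelling gene Ehd1. Camera gave an adjusted p of 3.36e-11 for them, and the adjusted p = 0.166 with an estimated correlation. Negative regulators of the pathway rose in 17 of 23, among them the phosphatase Dusp5 (5.61), the ribonuclease Zc3h12a (3.48), Socs3 (3.44) and the kinase-like Irak3 (2.42), while 4 fell, including Gpnmb (-2.38) and the lipid phosphatase Inpp5d (-0.66). Their camera adjusted p was 0.000328, and the adjusted p = 0.203 with an estimated correlation. The components of the Tlr4 pathway itself moved both ways, with 11 of 31 higher and 10 lower, or 7 higher and 16 lower with scaling by library totals and 8 and 14 on TPM values, and camera did not call the list at an adjusted p of 0.919. Its coreceptor Cd14 rose 5.46-fold to 2903 ± 332 CPM, and the kinase gene Irak2 rose 3.96-fold, whereas Irak1 (-1.08) and the adaptors Ticam2 (-0.93) and Myd88 (-0.65) fell. Tlr4 had mean levels of 87.6 CPM in None and 92.6 CPM in LPS and was not called, with an adjusted p of 0.606 by edgeR's quasi-likelihood test. The log2 fold change of Tlr4 was 0.08 and became 0.25, with an adjusted p of 0.0346 in the same test, without LPS replicate 3, -0.10 without LPS replicate 1, and -0.18 with scaling by library totals. Ly96, the partner of Tlr4 at the cell surface, rose, and the log2 fold change of Ly96 was 0.63, or 0.38 with scaling by library totals, where edgeR's quasi-likelihood test gave an adjusted p of 0.0507 and the call was lost.

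Immediate early genes divided, with 14 of 25 higher and 6 lower. Fosl1 (5.57), Myc (5.43) and Ier3 (4.14) rose while Fos (-2.03), Egr3 (-1.98) and Btg2 (-2.34) fell. Camera called the list higher at an adjusted p of 0.0294, which became 0.0682 without None replicate 1, and the adjusted p = 0.648 with an estimated correlation. Nucleic acid sensors were also split, with 11 of 24 higher and 8 lower (9 and 12 with scaling by library totals, 9 and 9 on TPM values), and a camera adjusted p of 0.343. The cytosolic RNA sensors Ifih1 (3.52) and Ddx58 (2.53) and the DNA-responsive Ifi204 (4.22) rose, whereas the endosomal receptors Tlr8 (-3.84), Tlr9 (-1.94), Tlr13 (-1.93) and Tlr7 (-1.75) fell. On DESeq2's statistics camera called this list higher, with an adjusted p of 7.71e-06. Of 18 genes of the small RNA machinery, 6 rose and 8 fell (3 and 12 with scaling by library totals, 2 and 11 on TPM values), with Tnrc6c (-1.19), the microRNA processing factor Dgcr8 (-1.07) and Ago4 (-1.02) lower and the RNA editing enzyme Adar (0.90) higher. Camera did not call that list, with an adjusted p of 0.599.

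**Figure D2:**
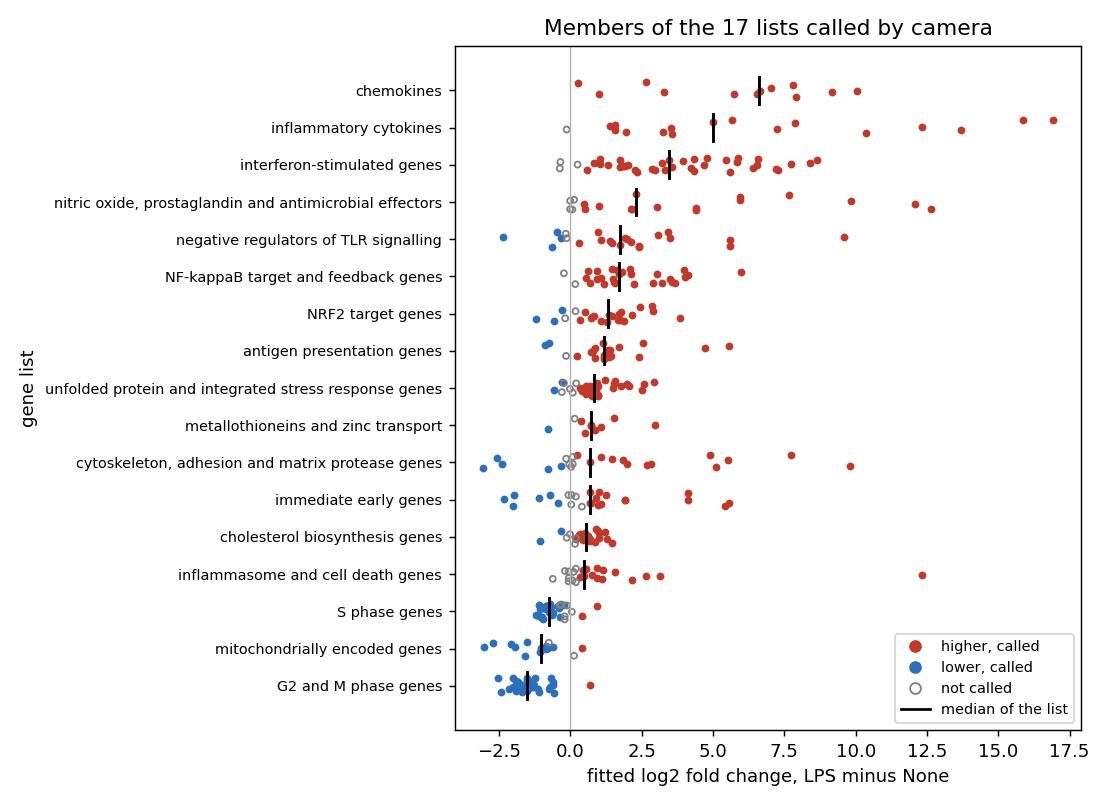
Fitted log2 fold changes (LPS minus None) of the tested members of the 17 gene lists called by camera, 1 point per gene, with called genes filled and uncalled genes open, and the median of each list as a black bar. The medians run from -1.51 for G2 and M phase genes to 6.60 for chemokines; fitted values of genes with 0 counts in None, such as Csf3, depend on the prior count of the fit.

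Antigen presentation genes rose in 19 of 22, with the checkpoint ligand Cd274 (4.72), the costimulator Cd80 (2.56) and the class I genes H2-T23 (2.42) and H2-K1 (1.16), while the class II chaperone H2-DMa (-0.76) and the protease Ctss (-0.89) fell. Camera gave an adjusted p of 7.22e-06, and the adjusted p = 0.314 with an estimated correlation. Class I genes are close relatives that can share reads. The 5 members with too few counts for a test were the class II genes H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 and their regulator Ciita. Together they went from 48 counts in None to 8 in LPS, with up to 12 for a gene in a single library. Cytoskeleton, adhesion and matrix protease genes rose in 13 of 23 and fell in 5, with an adjusted camera p of 0.0294 and an adjusted p = 0.545 with an estimated correlation. The gelatinase Mmp9 rose 888-fold to 131 ± 36.1 CPM, and osteopontin (Spp1) rose 45.8-fold from 933 ± 184 to 42750 ± 3230 CPM and held the largest share of counts in each LPS library, whereas the integrin genes Itga4 (-3.05) and Itgax (-2.40) fell. Inflammasome and cell death genes rose in 14 of 23 and none fell (11 higher and 5 lower with library totals, 10 and 4 on TPM values), among them the necroptosis effector Mlkl (2.66), the membrane rupture protein gene Ninj1 (2.15) and the survival gene Bcl2l1 (3.15). Their camera adjusted p was 0.000679, and the adjusted p = 0.166 with an estimated correlation. Alternative activation genes were higher in 8 of 12 and lower in 3, with Ccl22 (6.54) and the scavenger receptor Cd36 (5.85) up and Clec7a (-3.01) and Trem2 (-2.32) down. The camera adjusted p of that list was 0.141, and the list was called higher without None replicate 2 (0.0302), without None replicate 3 (0.0283), without a filter on low counts (0.0207), on unfiltered TPM values (0.01) and with scaling by library totals (0.0143).

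Macrophage identity genes went both ways, with 12 of 27 higher and 10 lower (11 and 10 with scaling by library totals, 9 and 10 on TPM values) and a camera adjusted p of 0.536. The scavenger receptor Msr1 (2.57) and the transcription factor Cebpb (1.98) rose, and the chemokine receptor Cx3cr1 (-1.58) and the growth factor receptor Csf1r (-1.33) fell. Osteoclast genes were higher in 7 of 15 and lower in 3 (5 and 6 with library totals, 6 and 4 on TPM values), with Mmp9 and Src (5.99) up and Ocstamp (-1.51) and Nfatc1 (-1.43) down, at a camera adjusted p of 0.510. Of 11 complement and coagulation genes, 6 rose, including the urokinase receptor Plaur (4.78) and the properdin gene Cfp (1.20), and 4 fell, including the coagulation factor gene F10 (-0.96). With library totals 4 were higher and 4 lower, and on TPM values 3 and 3. Camera did not call them at an adjusted p of 0.467, and called them higher on DESeq2's statistics at 0.00274.

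Genes of the response to oxidants and metals rose. NRF2 target genes were higher in 19 of 24 and lower in 3, with the cystine carrier Slc7a11 (3.83), the ferritin heavy chain Fth1 (2.90) and heme oxygenase Hmox1 (2.88) up and Osgin1 (-1.21) down. Fth1 reached 20150 ± 1800 CPM. Metallothionein and zinc transport genes were higher in 8 of 10, with Mt2 at 2.97 and Mt1 at 1.08, and lower only for Slc30a5 (-0.80). Genes of the unfolded protein and integrated stress responses rose in 25 of 32, among them Chac1 (2.93), asparagine synthetase Asns (2.58) and Ddit3 (2.51), while Xbp1 (-0.58) fell. Cholesterol biosynthesis genes rose in 18 of 24, with the enzymes Hsd17b7 (1.45) and Msmo1 (1.01), and 2 fell, including the sterol sensor Insig1 (-0.33). Camera's adjusted p-values for these 4 lists, in that order, were 6.12e-06, 0.00791, 9.14e-06 and 0.00142. The first had an adjusted p = 0.166 with an estimated correlation, the next pair an adjusted p = 0.314 with an estimated correlation, and cholesterol biosynthesis an adjusted p = 0.648 with an estimated correlation.

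Other metabolic lists had members on both sides and were not called by camera. LXR target and sterol efflux genes were higher in 8 of 18 and lower in 8 (4 and 10 with scaling by library totals, 3 and 10 on TPM values), with Cd36 and Plin2 (1.47) up and Smpdl3a (-2.00) and Apoe (-1.77) down. Lysosome and endocytosis genes were higher in 14 of 33 and lower in 9 (10 and 15 with library totals, 10 and 12 on TPM values), with the protease genes Ctsl (2.54) and Ctsd (1.38) up and the transcription factor Tfeb (-1.29) down. Of 29 glycolysis and hypoxia genes 15 rose, with the glucose carrier Slc2a1 (1.99), Hif1a (1.79) and Ero1l (2.77), and 8 fell, with Pdk1 at -1.48, or 9 and 10 with library totals and 10 and 10 on TPM values. Nuclear genes of oxidative phosphorylation were higher in 12 of 35, led by cytochrome c, Cycs (0.99), and lower in 7, with Ndufb5 at -0.49, but the balance turned to 4 higher and 21 lower with scaling by library totals and to 4 and 19 on TPM values. Citric acid cycle genes were higher in 7 of 22, such as Mdh2 (1.07) and Ogdh (1.05), and lower in 7, such as Idh3g (-0.66), or 5 and 12 with library totals and 6 and 12 on TPM values. Heat shock genes were higher in 6 of 16, including Hsp90aa1 (0.94), and lower in 3, including Hspa1b (-1.76), and this turned to 4 and 8 with library totals and to 4 and 7 on TPM values. Of 3 aryl hydrocarbon receptor genes tested, Tiparp (1.80) and Arnt (0.41) rose and the repressor Ahrr (-2.67) fell, with Arnt at 0.15 and not called under scaling by library totals. Camera's adjusted p-values were 0.921 for the LXR list, 0.366 for lysosome, 0.260 for glycolysis, 0.709 for oxidative phosphorylation, 0.937 for the citric acid cycle, 0.639 for heat shock and 0.616 for the aryl hydrocarbon receptor list. Leaving out None replicate 1 or LPS replicate 3 turned camera's direction for the citric acid cycle (medians -0.058 and -0.057), and leaving out LPS replicate 2 turned it for the LXR list (0.071). The medians of the lysosome, glycolysis, oxidative phosphorylation, heat shock, macrophage identity, Tlr4 pathway and nucleic acid sensor lists lay between 0.01 and 0.19 and were below 0 with scaling by library totals and on TPM values.

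Genes of the cell cycle were lower in LPS. Of 32 genes of G2 and M phase 31 fell, with a median log2 fold change of -1.51, and Cks2 (0.70) rose. The mitotic cyclin gene Ccnb2 (chromosome 9, 70407692 to 70421547) fell 5.79-fold, from 97.1 ± 9.26 to 16.8 ± 4.73 CPM. The kinetochore protein gene Cenpf fell 5.38-fold and the mitotic regulator gene Cdc20 4.40-fold. The proliferation marker Mki67 lay at -1.89. S phase genes fell in 24 of 32 with a median of -0.74, among them the helicase subunit Mcm7 (-1.10), Dtl (-1.09) and Ccne2 (-1.20), while Ccne1 (0.93) and E2f1 (0.41) rose. Camera gave adjusted p-values of 7.27e-08 for G2 and M phase and 0.000303 for S phase. The first had an adjusted p = 0.640 with an estimated correlation and the second an adjusted p = 0.678 with an estimated correlation. Of 20 p53 target genes 13 rose, including the death receptor Fas (3.95) and the cell cycle inhibitor Cdkn1a (1.52), and 4 fell, including Btg2 (10 and 6 with library totals, 8 and 5 on TPM values), with a camera adjusted p of 0.144. Replication-dependent histone genes were mostly under the filter on low counts, and of the 2 tested H1f2 (0.43) was higher and H4c9 (-0.63) lower. The log2 fold change of H1f2 was 0.30 without None replicate 1, 0.46 without None replicate 2, 0.33 without LPS replicate 1, 0.31 without LPS replicate 3 and 0.17 with scaling by library totals, and its call was lost in each of these and on TPM values. The H4c9 call was lost with DESeq2, at a log2 fold change of -0.61 and an adjusted p of 0.054.

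Ribosomal protein genes moved little, with 2 of 46 higher and 5 lower, such as Rpl32 (-0.38), and none called when adjusted over the list alone. Camera's adjusted p was 0.468, and the list was called lower on TPM values (0.0078) and with scaling by library totals (0.0143), where its median was -0.27 and -0.31 and its members were 0 higher and 34 lower on TPM values and 0 higher and 37 lower with library totals. Ribosome biogenesis and MYC target genes were higher in 9 of 31 and lower in 14 (6 and 20 with library totals, 7 and 20 on TPM values), with a camera adjusted p of 0.805. Myc itself rose 43.1-fold and Odc1, the first enzyme of polyamine synthesis, rose 38.9-fold to 5454 ± 1230 CPM, whereas the nucleolar genes Dkc1 (-0.59) and Ncl (-0.49) fell. The median of this list was -0.16 and its mean 0.28. Mean, median and camera's direction also differed in sign for the LXR list (median 0.02, mean -0.10), the citric acid cycle list (median -0.03, mean 0.07) and the aryl hydrocarbon receptor list (median 0.41, mean -0.15).

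Mitochondrially encoded genes fell in 12 of 15, with a median log2 fold change of -1.03, a camera adjusted p of 0.000945 and an adjusted p = 0.314 with an estimated correlation. The share of all counts on the mitochondrial genome was 4.08 ± 0.22% in None and 2.55 ± 0.13% in LPS (SD, n = 3). That share leaves out counts assigned to nuclear copies of these genes. Summed with its copy, mt-Co3 went from 313 to 7645 CPM in None and from 185 to 4287.5 CPM in LPS. Cytochrome b, mt-Cytb (14145 to 15288 of the mitochondrial genome), fell 6.56-fold from 4714 ± 350 to 718 ± 61.0 CPM. The respiratory complex subunit genes mt-Nd2 and mt-Nd1 fell 4.21-fold and 3.81-fold. The log2 fold change of mt-Nd3 was -3.04, or -3.67 without LPS replicate 2. The most abundant, mt-Co1, was not called at 0.13, was called at 0.20 without LPS replicate 2, and lay at -0.13 with scaling by library totals, and the ribosomal RNA mt-Rnr1 rose by 0.42, a call that was lost with that scaling at 0.16. The call of mt-Co2 (-0.87) was lost without None replicate 3 (-0.75) or LPS replicate 2 (-0.95), and mt-Co3 (-0.76) was called lower without None replicate 2 (-1.12) or LPS replicate 1 (-1.24). Several of these genes share sequence with nuclear copies. All 31-mers of mt-Co2 lie in such copies, and its 126 CPM in None became 8088 CPM when summed with them, so single values of mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l are uncertain.

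**Figure D3:**
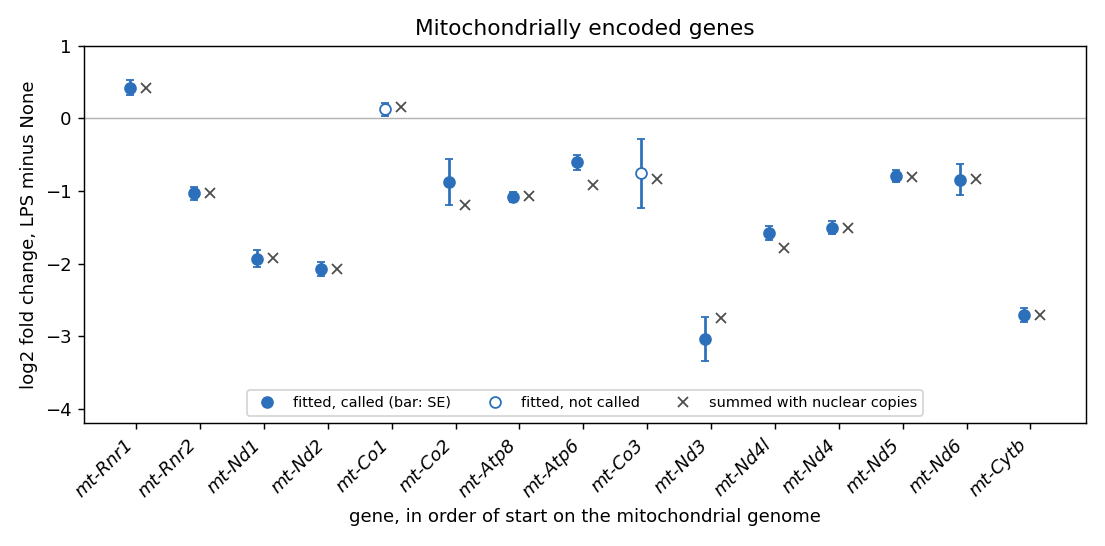
Log2 fold changes (LPS minus None) of the 15 mitochondrially encoded genes in the order of their start on the mitochondrial genome. Circles are fitted values with their standard errors, filled where called, and crosses are log2 ratios of the group means after the counts were summed with nuclear copies that share at least 5% of the 31-mers; the fitted values range from -3.04 for mt-Nd3 to 0.42 for mt-Rnr1, and mt-Co1 at 0.13 turns negative with scaling by library totals.

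Markers of other cell types were few. None of the 11 epithelial and 9 erythroid markers had enough counts to be tested, with totals over the list of 28 counts in None and 2 in LPS for the epithelial and 20 and 17 for the erythroid markers. Among fibroblast markers only Pdgfrb was tested and fell (-1.91), while the 12 markers with too few counts for a test went from 15 counts in None to 89 in LPS, with up to 34 for a marker in a single library. Among T and NK cell markers only Lck was tested and rose (1.53). The B cell markers Ighm (-1.85) and Cd79a (2.47) went opposite ways, as did the neutrophil markers S100a8 (6.71) and Csf3r (-2.69). Of 3 dendritic cell markers tested only Itgax was called, lower, and camera gave an adjusted p of 0.535.

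Of 35 lists tested with camera, 17 were called, 14 higher and 3 lower, and none of these calls held with an estimated correlation. Fry, used here in its directional form, asks whether members change in a common direction, not whether they change more than other genes. It gave these 17 lists adjusted p-values from 5.95e-06, as for chemokines, to 0.0122 for S phase genes. With most genes changed, fry also called lists that camera did not, such as Tlr4 signalling components at an adjusted p of 0.0242. The medians of the 17 lists kept their sign with size factors of DESeq2, with scaling by library totals and on TPM values. Adjusted over the list alone, 36 interferon-stimulated genes were higher and 1 lower, 27 NF-kappaB genes higher and 1 lower, 20 NRF2 genes higher and 3 lower, 25 stress response genes higher and 3 lower, 11 oxidative phosphorylation genes higher and 5 lower, and 6 citric acid cycle genes higher and 7 lower. Apart from these and the ribosomal proteins, the counts were the same as those over all genes tested.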

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

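Of the alternatives given here, scaling by library totals alone was chosen after the data were seen; the others were planned. The total of genes changed lay within 1.5 times of 8232 in all 15 settings, from 7383 on log2(TPM + 0.1) to 8777 without a filter, and from 7507 to 8103 when each library was left out in turn. The number of lists called lay between 16 and 19. The number of genes higher in LPS was 4052 and became 2637 on log2(TPM + 1) with a mean TPM of at least 1, 2626 on log2(TPM + 0.1), and 2679 with library totals. The number at least 2-fold higher was 1327 and became 826 on log2(TPM + 1) with the filter and 843 without it. The median over genes of the shift in log2 fold change was -0.26 with library totals and -0.20 on TPM values. The shift with library totals follows from leaving out the TMM factors, which ran from 1.083 to 1.103 in None and from 0.899 to 0.941 in LPS. TPM values sum to 1000000 per library and were also fitted without TMM factors. How much of the shift on TPM values follows from that was not tested. Single genes had other shifts there, and their cause was not tested.

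Of 158 named genes 149 and of 35 lists 24 kept their direction and side of the threshold in every setting. Among these, reversals were found for Tlr4 and 6 lists that were not called in any of the settings that reversed them. With library totals the reversal of Tlr4 follows from leaving out the TMM factors, and the cause of the others was not tested. Of 583 called members of all lists, 18 took the other sign with library totals, 7 of them genes of oxidative phosphorylation, and 12 on log2(TPM + 1) with a mean TPM of at least 1, with 0 of them called there. The log2 fold change of Tlr4 was -0.12 on log2(TPM + 1) with or without a filter, -0.13 on log2(TPM + 0.1), -0.10 without LPS replicate 1 and -0.18 with library totals, while it was 0.25 and called without LPS replicate 3. Camera's direction turned for heat shock genes on TPM (medians -0.16, -0.16 and -0.14) and for oxidative phosphorylation (-0.21 on each TPM scale, -0.25 with library totals). It turned for the citric acid cycle on TPM (-0.24, -0.25 and -0.24), without None replicate 1 (-0.058), without LPS replicate 3 (-0.057) and with library totals (-0.29), and its median ranged from -0.058 to 0.016 (without None replicate 3) when libraries were left out in turn. With TMM scaling and all 6 libraries, camera's direction was lower for LXR targets (median 0.02) and ribosome biogenesis (-0.16). For LXR targets it turned to higher with DESeq2 (median 0.032), without LPS replicate 2 (0.071) and with library totals, where the median was -0.24. The LXR median ranged from -0.015 (without LPS replicate 1) to 0.071 over the libraries left out. For ribosome biogenesis camera's direction turned to higher with DESeq2, at a median of -0.14. For Tlr4 signalling components it turned to lower on unfiltered TPM, at a median of -0.14.

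No clear pairing of the libraries by replicate number was seen. Same-numbered libraries correlated in their deviations from the group means at 0.082, -0.02 and 0.01, and other pairs at -0.061 to 0.068. Not every library correlated best with its own number. With 3 libraries per group these deviations depend on each other, so the correlations cannot exclude a shared day or batch. A fit with the replicate number as a block called 8362 genes, of which 8159 were shared with the fit without it, and 17 lists.

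The 6 libraries make 10 splits into 3 and 3, which are too few for a share under 0.05. The real split gave 8232 genes and the highest other gave 0 by edgeR, while the other splits gave 9 to 57 genes at an unadjusted p under 0.05 and 0 or 1 by DESeq2. Every other split put None and LPS libraries on both sides, so the LPS difference entered its spread and few calls were bound to follow. The contrast of these counts therefore says nothing about chance. At this depth genes with few counts limit what can be said. In simulated data 40% of changes of 0.5 on the log2 scale were recovered. Those changes were not confined to genes with few counts, and far fewer genes changed there, so that share is not an estimate for these data.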

Other observations

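The test of scaling and the test of transcript length for the mitochondrial genes, and the test of counts summed with nuclear copies, were chosen only after the result was seen; the genes named here were chosen after their values were seen.

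Strongly induced genes formed runs along chromosomes, with 14 runs of 3 or more neighbouring tested genes that each rose at least 4-fold. The longest held 9 genes on chromosome 11 (83511736 to 83752642, GRCm38), among them the chemokine genes Ccl5, Ccl9, Ccl6, Ccl3 and Ccl4 and the protease inhibitor genes Wfdc17 and Wfdc21. Ccl3 rose from 43.0 ± 12.3 to 4340 ± 807 CPM and Ccl9 from 304 ± 12.6 to 2983 ± 124 CPM (SD, n = 3). A run on chromosome 10 held Ddt and the glutathione transferase genes Gstt3, Gstt1 and Gstt4, and a run on chromosome 16 held the cystatin family genes Cstdc4, Csta3, Stfa2 and Stfa3. Members of a family can share reads, so their single values are uncertain. Other runs held Clec4n, Clec4d and Clec4e on chromosome 6 and Slfn2, Slfn1 and Slfn4 on chromosome 11.

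Among long non-coding genes the largest increase was that of Mir155hg, the host transcript of the inflammatory microRNA miR-155, which went from 0.104 to 16.9 CPM with a log2 fold change of 7.23. Of 543 long non-coding genes tested, 108 were higher and 248 lower, with a median log2 fold change of -0.46.

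Strongly induced genes lay next to each other in 90 pairs, where 10000 permutations gave a mean of 22.5 and a maximum of 44 (permutation p = 0.0001, the smallest they can give). Reads shared between gene copies are argued against as the whole source, since 52 pairs with no shared 31-mer and different symbol stems remained, against a mean of 21.5 and a maximum of 43 (permutation p = 0.0001). Overlap or read-through into a close neighbour is argued against too, since 35 of these pairs lay at least 5 kb apart, against a mean of 14.3 and a maximum of 32 (permutation p = 0.0001), Osm with Lif and Kctd12 with Acod1 among them. Read-through over longer distances and relatives with different symbols, such as Csta3 with Stfa2, stay open. A hypothesis is that LPS may act on shared regulatory regions of neighbouring genes, which no value here tests.

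Mitochondrially encoded genes fell by unequal amounts, with log2 fold changes that spanned 3.46 over the 15 genes. That range is the pattern itself and leaves open how much a difference in scaling between libraries adds to the fall of all of them. Reads shared with nuclear copies are argued against for the 3 genes with under 5% of their 31-mers in a nuclear transcript, mt-Nd1, mt-Rnr1 and mt-Rnr2, which still spanned 2.35, and for the other 12 genes the range was 2.91 after the counts of the copies were added. The 6 protein-coding genes of at least 900 nt spanned 2.84, from mt-Cytb to mt-Co1, but they differ in length too and cannot settle a loss of short RNA. Among them mt-Nd1 (957 nt), mt-Nd2 (1038 nt) and mt-Cytb (1144 nt) fell more than mt-Nd4 (1378 nt), mt-Co1 (1545 nt) and mt-Nd5 (1824 nt). Over all 15 genes that order did not hold, with mt-Rnr1 (955 nt) at 0.42 and mt-Atp8 (204 nt) at -1.08. Loss of short RNA stays open. A difference in selection of polyadenylated RNA was not tested and stays open.

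Long non-coding genes were lower than protein-coding genes of the same expression by -0.17 (95% bootstrap interval -0.37 to -0.02), where the matched coding genes had a median of -0.29. Low expression could account for part of the decrease, and the interval for what it leaves unexplained excluded 0 but was close to it and did not pass the bounds set beforehand, so whether low expression is the whole source was not decided. Reads of overlapping or nearby coding genes stay open as well, since over the 121 non-coding genes at least 10 kb from any tested coding gene the difference was -0.04, with an interval from -0.31 to 0.25. Neither can be told apart from an effect of LPS on non-coding transcripts at this number of genes.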
